A study of Homo sapiens with 6 samples.

How the data were processed

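Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in H1155, a human lung carcinoma cell line. Per the labels, the libraries were prepared with the Omni-ATAC protocol as biological triplicates of control cells and of cells that express a chimera. The sample titles call the chimera libraries TA, and the labels do not say what TA or the chimera is. Each of the 6 libraries had 1 deposited peak list in MACS2's narrowPeak form, per the file names, so peaks were called per library and not on pooled replicates. The MACS2 version and settings, the aligner, the read filters and any shift of reads for the transposase are not given in the sources used here. The submitters' processing notes name HOMER 4.9 and the build GRCh38 without a role for either.

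The deposited fold of each peak is the authors' ratio of the pileup at the summit to the library's own local background, as MACS2 defines that column. The deposited −log10 p and −log10 q are MACS2's, computed within a library, and the least significant q seen in any list was 0.0407. The authors' fold and q describe, rank or filter peaks within a list. Tests of fold and q between region sets were computed and count in the family of adjusted p-values, but are not reported, since these values are relative to each library's own background. No list holds a value where no peak was called, so presence of a peak per library was the measure compared between groups. A region without a peak in a library lay below that library's calling threshold and can still have held signal.

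The coordinates did not match the named build. A summit lay within 500 bp of 5.60% to 6.67% of 39948 protein-coding gene ends of the GRCh38.p14 table in the 6 lists, against 3.18% to 3.92% after a shift by 5 Mb. In each list the share exceeded 20% in 12 of 300 bins of 10 Mb. Peaks ran past the last protein-coding gene of the table on 16 of 23 chromosomes, which can also occur on a matching build and does not by itself show a mismatch. Positions are therefore given as the deposited lists hold them, counted from 1, with the build left open, and no region was linked to a gene. The planned analyses of promoter position, gene lists (cell type markers among them), motifs and named genes needed a matching annotation or genome and were not run.

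Depth was taken from the peak lists. The pileup at each summit was recovered from the deposited fold and −log10 p under MACS2's Poisson model, to a tolerance of 0.005 in −log10 p, for over 99.9% of peaks in each list. The genome-wide background of the libraries recovered in this way ranged from 2.53 to 3.77 and the lowest summit pileup from 9 to 12. Total read counts were not used here. These values stand in for depth only if the MACS2 settings were the same in each library, which the sources do not state. They do not give the error of a single region.

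Peaks on chromosomes 1 to 22 and X were used, which left out 0.0168% of peaks. Peaks of the 6 libraries were merged where they shared at least 1 bp. A library had a region if any of its peaks overlapped it. A region was gained if it had a peak in 3 of 3 chimera libraries and in 0 of 3 control libraries, and lost in the opposite case. It was strong if the strongest peak in each of those 3 libraries had a −log10 q of at least 10. Mixed regions were called in exactly 3 libraries drawn from both groups. The named regions were the 10 gained and the 10 lost regions with the highest rank, ranked by the lowest −log10 q among the 3 libraries with the region. The rule fixed before the data were examined also asked for a linked gene, which was dropped because of the build.

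Values per library were compared with a two-sided exact permutation test, which with 3 libraries against 3 cannot give a p below 0.1. Pairs of lists were compared by the Jaccard index in bp. The design, these definitions and the settings of the counts were chosen before the data were examined. The following were added afterwards. The expected number of regions in each pattern came from a conditional model with 1 strength per region and 1 sensitivity per library, fitted on regions called in 1 to 5 libraries. Its intervals of 95% came from 1000 bootstrap draws of 1 Mb blocks, and from 200 draws in the alternatives. Region sets were compared with Fisher's exact test or permutation tests with 100000 resamples. Clustering was compared with 10000 random draws from regions called in exactly 3 libraries. The alternatives used 1000 draws, and the counts of neighbours 10 to 100 kb away used 2000. Adjusted p-values are Benjamini-Hochberg values, at a threshold of 0.05. Tests over regions have regions and not cultures as units, so their p-values and intervals describe these 6 libraries.

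The fit was checked on simulated calls of 149765 regions in 20 simulations, with fewer bootstrap draws than the main fit. The calls were drawn from the fitted model itself, so a ratio near 1 without a group effect was built in. The check covers the fitting, and not the case where the assumption of 1 sensitivity per library fails. Without a group effect the mean ratio was 0.988 for gained and 1.01 for lost regions, and 0 of 40 lower bounds lay above 1. With 500 regions planted in each direction the mean excess was 461 gained and 447 lost regions, and 40 of 40 lower bounds lay above 1. The alternatives were stricter peak thresholds, lists of equal length, a minimum cover, fixed windows at summits, a looser call rule, the replicate number as a block and each library left out in turn. Wider merging, other fits of the sensitivities and other distances were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.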

Results

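The accessible chromatin of H1155 lung carcinoma cells was profiled in 3 control libraries and 3 libraries of chimera-expressing cells, to ask which regions were open in one state and not in the other. The control lists held 101281, 85745 and 109339 peaks for replicates 1, 2 and 3, and the chimera lists 94500, 98999 and 99675. The recovered background pileup, taken to stand in for depth, was 2.53, 2.94 and 3.05 in the control libraries and 3.21, 2.74 and 3.77 in the chimera libraries. It did not differ between groups beyond the replicate spread (exact permutation test, two-sided, p = 0.4; the smallest p that 3 against 3 allows is 0.1).

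The amount of chromatin called as open overlapped between control and chimera libraries. The mean number of peaks was 98773 ± 11992 in control and 97707 ± 2812 in chimera libraries (SD, n = 3 each, exact permutation p = 0.8). Peaks covered 46.4 ± 7.47 Mb in control and 45.0 ± 1.49 Mb in chimera libraries (SD, n = 3 each, exact permutation p = 0.8). The control libraries spread more widely than the chimera libraries, since control 2 had the fewest peaks of the 6 and control 3 the most. The difference in peaks, chimera minus control, was −1065 with all libraries and −7587 without control 2, where both remaining control libraries lay above every chimera library (exact permutation p = 0.1, the smallest possible). Its sign turned to +182 without control 1, +4209 without control 3 and +546 without chimera 1.

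Most regions open in every library of one group were open in every library of the other. The 6 lists merged into 149765 regions, of which 56679 (37.8%) were called in all 6 libraries and 44444 in 1 library alone. All 3 control libraries shared 65875 regions, of which 86.0% were called in all 3 chimera libraries and 1197 (1.82%) in none. All 3 chimera libraries shared 65944 regions, of which 86.0% were called in all 3 control libraries and 930 (1.41%) in none. The mean Jaccard index was 0.627 within groups and 0.612 between groups, a difference of 0.0153 (exact permutation over 10 splits, p = 0.1, the smallest possible). The chimera pairs lay between 0.628 and 0.632, the control pairs between 0.596 and 0.665 and the pairs across groups between 0.594 and 0.624. Control 1 with control 2 (0.613) and control 2 with control 3 (0.596) lay inside the range across groups.

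In chimera-expressing cells 930 regions were gained and 1197 were lost, together 18.7% of the 11390 regions called in exactly 3 libraries. The strong sets held 34 gained and 55 lost regions. No single region was tested. The lists hold no value where no peak was called, and Fisher's exact test of presence in 3 libraries against 3 cannot give a p below 0.1. A model with 1 sensitivity per library, added after the data were seen, expected 478 gained and 502 lost regions. The observed numbers were 1.95 times (95% interval 1.83 to 2.06) and 2.39 times (2.27 to 2.51) those, an excess of 452 gained and 695 lost regions. The 18 mixed patterns of 3 libraries ranged from 0.532 to 1.18 times their expectation. Fitting the sensitivities on regions in exactly 3 libraries instead gave ratios of 2.71 for gained and 1.87 for lost regions. Both lay outside the intervals above, which do not cover the choice of fit. The size and the order of the excesses depend on that choice. With the main fit and peaks of −log10 q of at least 10 alone, the gained regions were 4.21 times and the lost regions 2.35 times the expectation. Weaker peaks were left out of all libraries before merging there, so those 482 gained and 831 lost regions can hold weaker peaks in the other group.

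**Figure D1:**
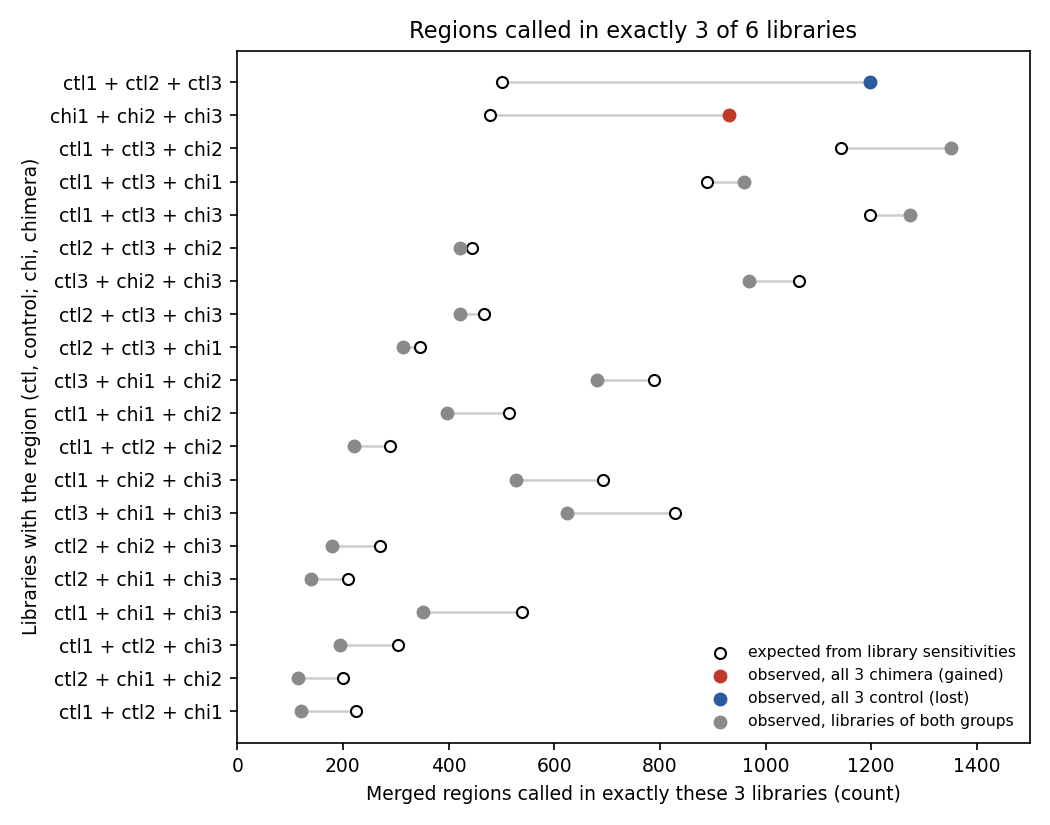
Number of merged regions called in exactly the 3 libraries named on the vertical axis (filled points) and the number expected from library sensitivities (open points); the horizontal axis is a count of regions. The patterns of all 3 control libraries (1197 against 502) and all 3 chimera libraries (930 against 478) lie farthest above their expectation.

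These counts rest on all 6 libraries, and a rule that needs fewer libraries lets more regions pass. Gained regions numbered 1540 without control 1, 2310 without control 3, 2190 without chimera 1, 1922 without chimera 2 and 1971 without chimera 3. Lost regions numbered 2278 without control 1, 4244 without control 2, 1784 without control 3, 1905 without chimera 1, 2143 without chimera 2 and 2150 without chimera 3. Strong gained regions numbered 79 without control 1, 172 without control 3, 113 without chimera 1, 92 without chimera 2 and 84 without chimera 3. Strong lost regions numbered 124 without control 1, 429 without control 2, 78 without control 3, 120 without chimera 1, 144 without chimera 2 and 136 without chimera 3. Both ratios to expectation were lower whichever library was left out, at 1.33 to 1.59 for gained and 1.65 to 1.91 for lost regions. With all libraries, lost regions outnumbered gained ones by 1.29 to 1, against 1.05 to 1 expected, a ratio of 1.23 (95% interval 1.13 to 1.33). Gained regions were more numerous without control 3, without chimera 1 and with lists of equal length (1106 gained, 1020 lost). A left-out library makes the rule unequal between the groups. Equal length dropped the least significant peaks of the longer lists before merging. Gained regions there can hold a deposited control peak, and lost regions a chimera peak. Over expectation, lost regions still led at 1.12 without control 3 and 1.35 without chimera 1. The ratio over expectation turned to 0.850 with peaks of −log10 q of at least 5 and to 0.902 with lists of equal length, so no direction is given for it.

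Among the gained regions, the one with the highest rank lay on chromosome 19 from 8303189 to 8303724, with a fold of 8.27, 6.72 and 6.36 in chimera libraries 1, 2 and 3 and no peak in the control libraries. All positions are those of the deposited lists, whose build is open, so no gene is named. A region on chromosome 2 from 177478309 to 177479318 had folds of 5.97 to 7.22 in the chimera libraries and lay 23.8 kb from the nearest region called in all 6. Over the 10 gained regions this distance ran from 1.15 kb (chromosome X from 153192216) to 122 kb (chromosome 10 from 834991). It was 2.14 kb for the region of highest rank. A region on chromosome 7 from 19652248 to 19652867 had folds of 6.42 to 7.49, and one on chromosome 10 from 834991 to 835701 folds of 5.36 to 8.01. The region on chromosome X from 41725037 to 41725469 had folds of 6.08 to 7.13. Those on chromosome 12 from 103791004 to 103791388 and on chromosome 16 from 80016229 to 80016595 had folds of 5.03 to 6.33 and of 5.87 to 6.95. The region on chromosome 15 from 41184105 to 41184370 had lower folds, of 3.55 to 4.31. A further 2 of the 10 were not gained once peaks up to 1 kb apart were merged: chromosome 2 from 218701074 to 218701479 (folds of 5.76 to 6.71) and chromosome X from 153192216 to 153192538 (folds of 2.56 to 2.81). The region on chromosome 2 from 177478309 was not gained when peaks had to cover 50% of a region.

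Of the 10 lost regions with the highest rank, 3 lay on chromosome 4 and 3 on chromosome 11. The folds of those on chromosome 4 in the control libraries were 6.19 to 8.69 from 844172 to 844874, 5.60 to 9.07 from 4408280 to 4409205, and 4.66 to 5.89 from 8046374 to 8046917. The region on chromosome 11 from 70951920 to 70952287 had folds of 7.11 to 9.15, and that on chromosome 13 from 67568179 to 67568861 folds of 7.08 to 8.63. The latter was not lost when peaks had to cover 50% of a region. The region on chromosome 7 from 27212559 to 27212824 had folds of 2.65 to 2.83. The highest rank of all lost regions fell to chromosome 1 from 156182944 to 156183235, with folds of 2.59 to 3.18, which lay 0.339 kb from a region called in all 6 libraries. That region and 3 more were not lost once peaks up to 1 kb apart were merged. The other three were on chromosome 11 from 94965335 to 94965739 (folds of 3.22 to 3.70) and from 65260099 to 65260342 (folds of 2.72 to 3.05), and on chromosome 1 from 41861767 to 41862267 (folds of 3.65 to 3.86). The region at 156182944 was also not lost with fixed windows at summits.

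**Figure D2:**
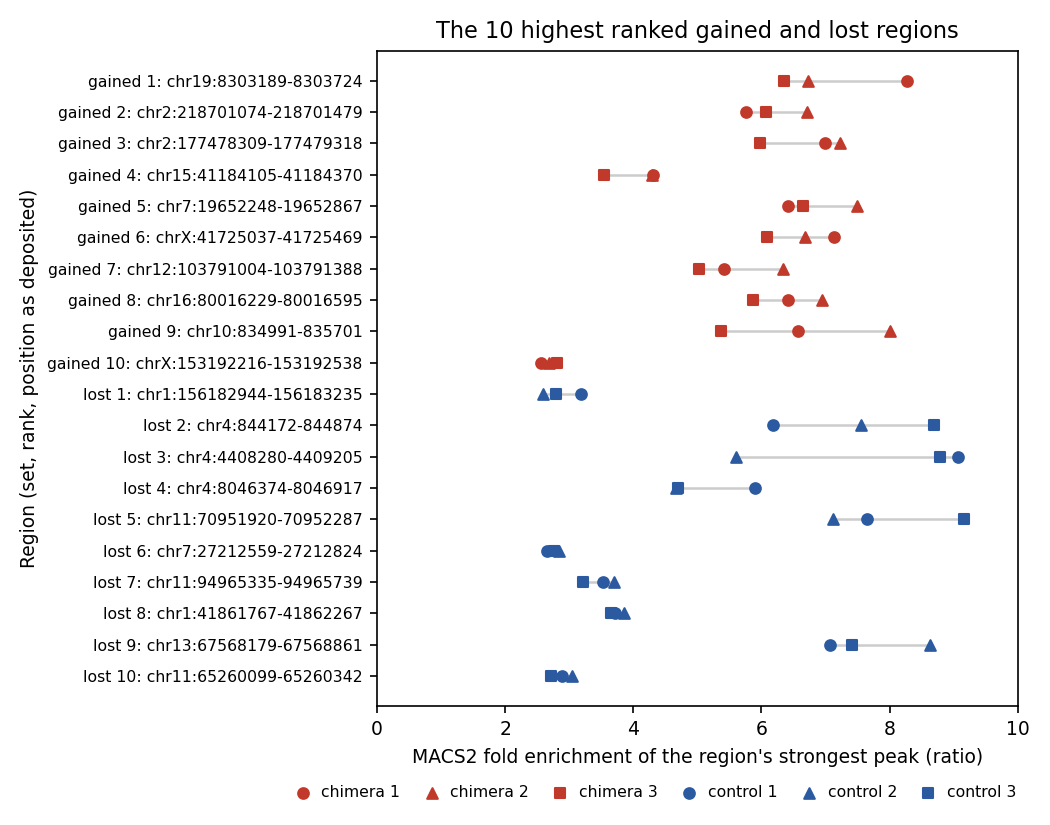
Fold over local background (ratio, horizontal axis) of the strongest peak in each library that has the region, for the 10 gained (red, chimera libraries) and 10 lost (blue, control libraries) regions of highest rank; marker shapes are replicates. The fold spans 2.56 to 9.15, and the libraries of the other group have no peak in these regions.

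Both gained and lost regions were wider than mixed regions, with a median width of 384.5 bp for gained, 354 bp for lost and 332 bp for mixed regions (permutation tests, 12 tests in the family, p = 1e-05 each, the smallest the permutations can give, adjusted p = 3e-05). Regions within 10 kb of one called in all 6 libraries made up 42.8% of gained, 51.5% of lost and 47.5% of mixed regions. The gained share was lower than the lost share (Fisher's exact test, two-sided, adjusted p = 0.000136). Among regions called in 1 library alone, 41.8% to 45.5% lay within that distance in the control libraries and 37.9% to 38.7% in the chimera libraries.

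Gained and lost regions were spread over all 23 chromosomes used. Their split between chromosomes did not pass the test (chi-square 32.8, 22 degrees of freedom, p = 0.0649, adjusted p = 0.0768). Chromosome 19 held 13 gained and 32 lost regions and chromosome 21 held 17 and 9. No chromosome passed Fisher's exact test of gained against lost after adjustment (lowest adjusted p = 0.347). Within 100 kb of another region of their own kind lay 113 gained regions, against 85.4 ± 12.1 (SD) in random draws of regions called in exactly 3 libraries, and 176 lost regions, against 139 ± 15.0. Of the gained regions 99 lay within 100 kb of a lost one, against 120 ± 9.74 in random draws. Each of the 3 comparisons had an adjusted p of 0.0194 (one-sided, permutation by random draws). The side was more than random for each kind's own neighbours and fewer than random for gained near lost. These tests and their sides were added after the data were seen. With neighbours 10 to 100 kb away alone, gained regions did not exceed random draws (one-sided permutation p = 0.119) and lost regions did (p = 0.0130). The gained count missed an unadjusted 0.05 without chimera 1 (permutation p = 0.0799) and without chimera 3 (permutation p = 0.0849), and the lost count did so at −log10 q of at least 10 (permutation p = 0.0709). The gained near lost count turned to 1.11 times random with fixed windows at summits and missed 0.05 in 5 more settings (permutation p = 0.0599 to 0.350). With regions called in at least 2 of 3 libraries the gained count also missed it (permutation p = 0.149).

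**Figure D3:**
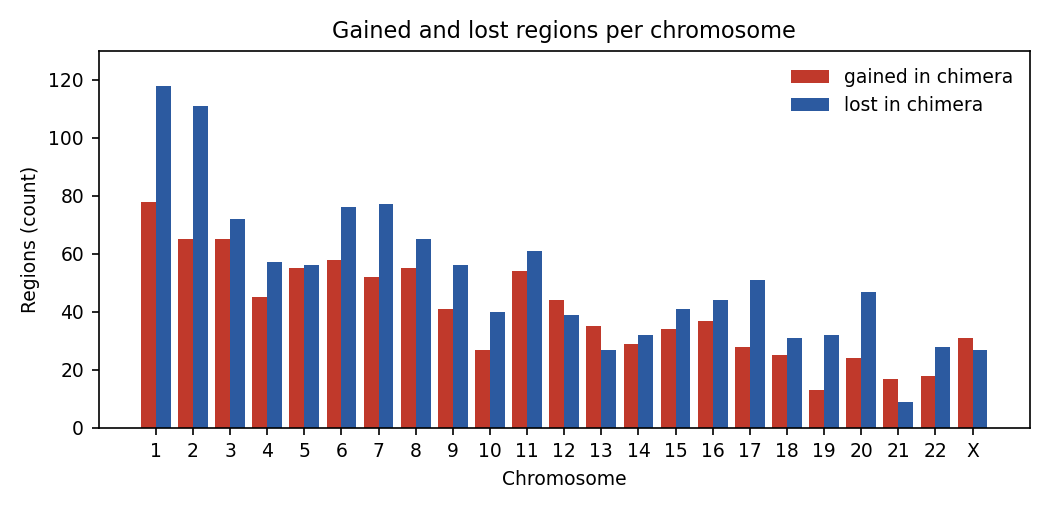
Number of gained (red) and lost (blue) regions on each chromosome, as a count. By ratio, lost regions outnumber gained ones most on chromosome 19 (32 against 13) and gained ones lead most on chromosome 21 (17 against 9).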

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

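The comparison with expected numbers, the neighbours and the clustering, and all their settings, were added after the data were seen, as were merging within 1 kb, other fits of the sensitivities and other distances. Gained and lost regions exceeded expectation in all 15 alternatives (gained 1.30 to 4.21 times, lost 1.52 to 2.77 times), and gained regions lay near shared regions less often than lost ones in all 14 (differences of -10.7 to -5.51 points). The counts moved with the threshold and the rule, as each changes what can pass. At −log10 q of at least 5 the strong counts were 59 gained and 89 lost, and at least 10 gave 482 gained (all strong) and 831 strong lost. Weaker peaks were left out before merging in both settings, so these regions can hold a weaker peak in the other group. Lists of equal length gave 1106 gained, 1020 lost, 90 strong gained and 77 strong lost, so gained led. Equal length left out the least significant peaks of the longer lists before merging. These regions can therefore also hold a weaker peak in the other group. Cover of 50% gave 172 strong gained and 269 strong lost, windows at summits 90 and 144, and merging within 1 kb 34 strong lost. At least 2 of 3 libraries against 0 gave 4170 gained, 5769 lost, 108 strong gained and 296 strong lost. Without 1 library, gained regions numbered 1134 to 2310, lost 1784 to 4244, strong gained 43 to 172 and strong lost 78 to 429. The difference in peaks, −1065 with all libraries, ranged from −7587 to 4209.

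The lost to gained ratio over expectation (1.23) reversed to 0.850 and 0.559 at −log10 q of at least 5 and 10, to 0.902 with lists of equal length and to 0.691 with sensitivities from regions in exactly 3 libraries. Without 1 library it was 1.04 to 1.35. The cause was not tested. Clustering of gained regions (1.32 times random) was 1.03 (permutation p = 0.149) at 2 of 3 libraries and 1.08 to 1.23 without 1 library. Clustering of lost regions (1.26) was 1.24 (permutation p = 0.0709) at −log10 q of at least 10. Gained near lost regions (0.827) reversed to 1.11 with windows at summits. It missed the threshold at 0.949 and 0.829 for −log10 q of at least 5 and 10, 0.906 with 50% cover, 0.883 with merging within 1 kb and 0.938 at 500 kb. The cause was not tested.

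Replicate numbers did not pair the libraries: correlations of same-numbered deviations were -0.00419, -0.0163 and 0.000788. With the replicate number as a block, all 3 numbers gave the same counts by construction, and at least 2 of 3 numbers gave 6344 gained, 8325 lost, 299 strong gained and 526 strong lost regions. Exact sign flips within numbers gave p = 1 for peaks and p = 0.25 for list overlap, where 0.25 is the smallest that 8 flips allow two-sided. The other settings meant for the gene list, motif and position analyses were not run, for want of a matching build. A region near the calling threshold can miss a call at this depth, so absence of a peak is not absence of open chromatin.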

Other observations

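The tests of chance splits and of pieces of one site were chosen or divided after their results were seen, and all patterns here were found in the same data.

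Relative to the numbers expected from library sensitivities, regions called in all libraries of one group and none of the other were more frequent than the mixed patterns of 3 libraries, though some mixed patterns held more regions (up to 1351). The tables argue against a difference in how readily a library calls regions that is the same at every strength. The lower of the gained and lost ratios to expectation was 1.95 and the highest mixed pattern reached 1.18. A difference between libraries that changes with strength was covered only in part, by sensitivities fitted on regions in exactly 3 libraries. That fit moved the ratios to 2.71 for gained and 1.87 for lost regions. Such a difference was not otherwise modelled and stays open. The expectations are scaled to the observed total of patterns of 3 libraries, so an excess of gained and lost regions itself lowers the mixed ratios. Splitting of peaks into pieces is also argued against: with peaks up to 1 kb apart merged the lower ratio was 1.91 (lower bound 1.81, highest mixed pattern 1.23). The real split gave 2127 regions and the highest other split 1491, and 89 strong regions against 67; only 1 of 10 splits, the real one, reached each value, and 10 splits are too few for a share under 0.05. The chimera may underlie the excess, but a preparation batch that follows the groups could do the same, and the labels give none to test.

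More regions were lost than gained with all libraries and peaks (1197 against 930), and fewer with lists of equal length (1020 against 1106). The latter left out the least significant peaks of the longer lists, so regions there can hold a weaker peak in the other group. If control libraries called more regions, the ratio of lost to gained over its expectation should be 1, and it was 1.23 (95% interval 1.13 to 1.33). By a bound written before this value was seen, such an interval counts against the explanation, but it covers neither the choice of threshold nor the fit of the sensitivities. Across the alternatives the ratio ran from 0.559 to 1.35. Its 95% interval lay below 1 at both stricter q thresholds, with lists of equal length and with sensitivities from regions in exactly 3 libraries. Control libraries averaged 98773 peaks and chimera libraries 97707 (exact permutation test, p = 0.8). Neither a real surplus of lost regions nor a higher call rate in control libraries is therefore established, and they cannot be told apart.

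Gained regions lay near gained ones and lost near lost ones. With neighbours 10 to 100 kb away alone, lost regions still exceeded random draws (one-sided permutation p = 0.0130), which argues against pieces of one site for them, and gained regions did not (p = 0.119), which leaves it open. A regional bias of single libraries also stays open: 2 mixed patterns reached the lower of the gained and lost ratios of 1.26, one of them (2.76) from 4 clustered of 120 regions. For copy number, the planned look was each chromosome's share of gained or lost regions among those called in exactly 3 libraries. The nearest tests run, gained against mixed and lost against mixed, missed the threshold (chi-square test, p = 0.0682 and 0.0768). Gained against lost missed it too (chi-square test, p = 0.0649). That leaves copy number open, and no further test of it was run.

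In regions called in 1 library alone, the lowest control share within 10 kb of a region in all 6 libraries exceeded the highest chimera share by 3.14 points (95% interval 1.35 to 4.92), the same direction as lost against gained regions. That was predicted if any region a control library calls lies nearer shared regions. This explanation therefore stays open for the difference between gained and lost regions.

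Of the 1 Mb windows, chosen after their values were seen, those with 5 gained regions lay on chromosome 11 from 19000001 to 20000000 and on chromosome 9 from 122000001 to 123000000. Those with 5 lost regions lay on chromosome 14 from 104000001 to 105000000 and on chromosome 17 from 48000001 to 49000000. A maximum of 5 did not exceed random draws for gained (p = 0.327, permutation) or lost regions (p = 0.711, permutation).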
